A study of Homo sapiens with 4 samples.

How the data were processed

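M14 is an established human melanoma cell line. Per the labels, it was stably transfected with an empty eGFP vector or with the same vector holding FLAG-tagged ARHGAP8, the coding region of a splice variant that lacks an exon. Each line was grown for 4 days on collagen-coated plastic (2D) or inside a reconstituted basement membrane gel (3D). Total RNA from each of the 4 combinations went onto 1 Affymetrix whole-genome array, so the number of arrays per group was 1 and limits the precision of every value. Per the labels' protocols, the RNA was reverse transcribed from a poly(T) primer and amplified by a pair of in vitro transcription rounds before labelling.

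The authors deposited 1 signal intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. Its version and detection calls were not given in the sources used here. The table held 54675 probe sets, of which 62 were AFFX control probe sets. The trimmed mean of the deposited intensity values, with 2% cut from each end, was 150.0 on each of the 4 arrays. Signal medians were 70.9 on the empty-vector 2D array, 68.3 on the ARHGAP8 2D array, 73.0 on the empty-vector 3D array and 77.1 on the ARHGAP8 3D array.

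The arrays were rescaled to a common 2% trimmed mean. Values below the median of all scaled values without control probe sets, a signal of 72.3, were set to that floor, and log2 was taken. Shares of probe sets above the floor were 49.4% and 48.4% on the 2D arrays of the empty-vector and ARHGAP8 lines, and 50.3% and 51.9% on their 3D arrays. A ratio with 1 side at the floor is a lower bound. Probe sets were named from the platform annotation, with symbols updated through the gene identifier in a RefSeq gene table for 41037 probe sets. In that annotation 41091 probe sets carried 1 gene symbol, 1801 carried several and 11721 carried none; those with several symbols named no gene. A gene was represented by the probe set, among those naming it alone, with the highest mean log2 value. Of 19775 genes, 14292 were above the floor on at least 1 array and count as measured, 13239 were above it on at least 2 arrays and were tested, and 11201 were above it on all 4.

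Single comparisons set 1 array against 1 array, carry no p-value and count genes at least 2-fold apart. The ratio between the lines in 2D and that in 3D share no array, nor do the 3D over 2D ratios of the lines, so agreement within each pair is the repeat the design holds. The test was an additive model of plasmid and culture in limma 3.58.1 under R 4.3.3, with eBayes and an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, which is the difference of differences. Its error covers array noise and any real interaction, and leaves out variation between separately made lines or cultures, since 1 line per plasmid was measured. Each standard error (SE) given is moderated by eBayes. With prior degrees of freedom of 19.4 it draws mostly on the variance of other genes of like signal. It is thus not the spread of that gene over its 4 arrays. The interaction itself has no residual degree of freedom and was not tested.

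The additive test was tested on simulated data, in 20 draws with 50 genes changed at each of 4 fold sizes per factor, on a mean of 13073 genes. The changed genes were drawn from those with a mean signal more than 2-fold above the floor, so the shares called hold for such genes. Noise was drawn without an interaction and with prior degrees of freedom of 30.4, against 19.4 in the fit of the measured values. For the plasmid term it called 26.9% of genes changed 1.5-fold, 86.3% of those changed 2-fold and 100.0% of those changed 4-fold; for the culture term these shares were 27.9%, 86.0% and 100.0%. More false calls came out than the nominal 5 in 100. On average 10.7% of plasmid calls were false, from 2.0% to 18.5% over the draws, and 11.8% of culture calls, from 2.1% to 21.8%. That was a mean of 19.6 false among 176.2 plasmid calls and of 22.1 among 178.9 culture calls; with no change simulated, a mean of 4.25 plasmid and 4.45 culture calls came out. These shares belong to the simulated number of changed genes and do not carry over to the measured counts. When the test was given the variance trend and prior degrees of freedom that the data were drawn with, these averages were 3.9% and 4.1%, and with the prior degrees of freedom alone 7.3% and 8.4%. The excess thus came with estimating the variance trend and prior degrees of freedom. Neither more residual degrees of freedom nor values without the floor were simulated, so their parts in it are not separated. Adjusted p-values near the threshold were on average too small in these draws, and those of the measured genes carry that limit.

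Before the data were examined, 40 gene lists were fixed with 1254 entries, as were the 2-fold rule, the test, the alternatives and the rule for the genes named. That rule took, per comparison, the 8 highest and 8 lowest genes above the floor on all arrays by the smaller of their 2 independent ratios, and the 4 highest and 4 lowest bounds. It also took 5 genes at each end of the difference of differences and up to 4 members of each list. In all, 111 list entries matched no probe set of their own. The values of 3 lists are not reported. A list stands apart when its median log2 ratio lies in the outermost 2.5 percent of 10000 random lists matched on size and mean signal, on the same side in both independent ratios. On simulated values, drawn independently for each gene, 0 of 300 unshifted lists and 300 of 300 shifted by 0.5 log2 stood apart. Members of a measured list can move together, and smaller shifts were not simulated. This check thus gives neither an error rate nor a power for the measured lists.

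The alternatives were quantile and cyclic loess normalization, floors at percentiles 25 and 60, a pseudocount of 16 without a floor, the mean of a gene's probe sets, fold thresholds of 1.5 and 3, eBayes without the trend and robust eBayes. A test on genes above the floor on all 4 arrays was added after the simulation, and counts without the ARHGAP8 3D array after its control signals were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Probe sets that name several genes were not analysed here except those of ARHGAP8.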

Results

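Gene expression was measured in M14 melanoma cells carrying either an empty vector or ARHGAP8, each in 2D and in 3D culture. The series title names cell motility as its subject. There was 1 array for each of the 4 combinations, so single ratios have no replicate error. Across probe sets the log2 signals of the lines correlated at 0.984 in 2D and 0.965 in 3D, and those of 2D and 3D culture at 0.965 in the empty-vector line and 0.958 in the ARHGAP8 line.

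ARHGAP8 itself could not be read. All 4 of its probe sets are also annotated to the readthrough gene PRR5-ARHGAP8. Their signals lay between 4.02 and 14.8 on the 4 arrays, below the floor of 72.3, so no fold is given. Where these probes lie relative to the coding region in the plasmid was not analysed here, so the signals do not check the labels, and the line is called the line labelled ARHGAP8. The ARHGAP8 3D array also differed in its control probe sets. The median signal of 18S ribosomal RNA was 626 there against 27.7 to 49.4 on the other 3 arrays, and that of 28S ribosomal RNA was 1390 against 94.4 to 119. The 28S medians fall on different probe sets from array to array. Its 5' and middle probe sets were raised, at 1390 and 1554 against at most 110 and 172. Its 3' probe set was not, at 124 against 119 to 138. These values stand beside every ratio that uses this array.

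**Figure D1:**
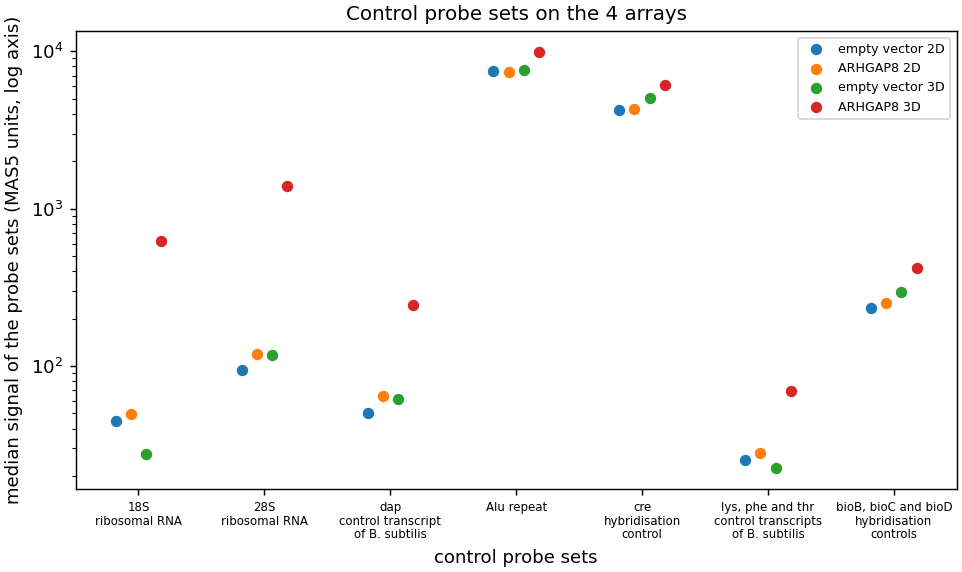
Median signal of 7 groups of control probe sets (log axis, MAS5 units) on each of the 4 arrays, 1 point per array. The 18S and 28S ribosomal RNA medians of the ARHGAP8 3D array, 626 and 1390, lie above those of the other 3 arrays.

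The first comparison asked how the line labelled ARHGAP8 differed from the empty-vector line. TYRP1, a melanosomal enzyme of pigment synthesis, rose in the line labelled ARHGAP8 by 1.10 ± 0.18 log2 (moderated SE, 4 arrays). Its adjusted p was 0.0107 in limma after Benjamini-Hochberg adjustment, with ratios of 1.07 in 2D and 1.13 in 3D. CXCL8, a neutrophil-attracting chemokine, rose by 1.15 ± 0.19 (0.98 and 1.32; adjusted p 0.00859 in limma with Benjamini-Hochberg adjustment), while its other probe set read 0.43. GPR143, a melanosomal receptor mutated in ocular albinism, fell by 1.49 ± 0.23, with ratios of -1.87 in 2D and -1.12 in 3D (adjusted p 0.00667 in limma with Benjamini-Hochberg adjustment). The mitochondrial carrier gene SLC25A23 fell by 1.09 ± 0.19 and the zinc finger gene ZNF106 fell by 0.99 ± 0.16. GOLIM4, which encodes a Golgi membrane protein, rose by 1.71 ± 0.25 and RAB12, a small GTPase of vesicle traffic, by 1.76 ± 0.27. Each rose far more in 3D (2.58 and 2.69) than in 2D (0.84 and 0.83), a gap that these moderated SEs understate. The other probe set of RAB12 read 0.15. MMP3, a secreted matrix protease, was higher by 1.45 in 2D and 0.81 in 3D and did not pass (adjusted p 0.0984 in limma with Benjamini-Hochberg adjustment).

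In all, 17 of 13239 genes passed the additive test for the plasmid, 9 higher and 8 lower. Besides those above, HLA-DRB4 rose by 1.11, although HLA-DRB paralogs are nearly identical and its value is uncertain. CTNNB1, which encodes beta-catenin, rose by 0.98, with 1 of its 2 other probe sets opposite. GPATCH1, at the floor in the empty-vector line, rose by at least 1.68 averaged over the cultures, with bounds of 1.66 in 2D and 1.69 in 3D. FASN, the fatty acid synthase gene, fell by 1.33 (-0.51 in 2D and -2.14 in 3D). TUBB4A, a tubulin gene, fell by 0.83. TRMT44, at the floor in the line labelled ARHGAP8, passed with a bound of -1.26 averaged over the cultures, from -1.14 in 2D and -1.38 in 3D. Passing genes outside the naming rule, named after their values were seen, were BCL10 and IRF2BPL, which rose by 1.08 and 1.21, and SKI and FCRLA, which fell by 1.00 and 1.11, FCRLA being at the floor on the ARHGAP8 2D array. Named genes that did not pass were MIX23 and MIS12, higher by 0.89 and 0.80, and BTBD2, HEBP1, PKNOX2 and PRKACA, at -0.92, -0.85, -0.78 and -0.91. Averaged over the cultures, the bounds of EHD3, ZNF575 and ADGRV1 were 1.11, 0.84 and 0.82, and those of CLK2, NEK2-DT and RB1-DT were -0.99, -1.07 and -0.85. In the culture with the smaller bound they were 1.04, 0.83 and 0.81, and -0.91, -0.86 and -0.81. The other probe set of EHD3 read 0.05 and that of PRKACA -0.15, averaged over the cultures. The plasmid calls depend on the processing: limma made 0 calls after either other scaling, with 997 genes under an unadjusted p of 0.05 after quantile and 1035 after cyclic loess normalization, and 61 on genes above the floor on all 4 arrays. In simulated data with no change the test made a mean of 4.25 plasmid calls, and with 50 genes changed at each of 4 fold sizes a mean of 19.6 false among 176.2, more than the 17 made here, so how many of the 17 are false is not known. With 1 line per plasmid a difference between the lines cannot be assigned to ARHGAP8.

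By size alone, 33 genes were at least 2-fold higher and 33 lower in the line labelled ARHGAP8 in 2D, and 151 and 180 in 3D. Meeting the rule in both cultures were 5 higher genes, where independent lists would share 0.349, and 4 lower genes, against 0.416; 2 genes met it in opposite directions. Without the ARHGAP8 3D array the rule rests on 2D alone, with 66 genes. Across 11201 genes, which are not independent replicates, the 2D and 3D ratios correlated at 0.111.

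**Figure D2:**
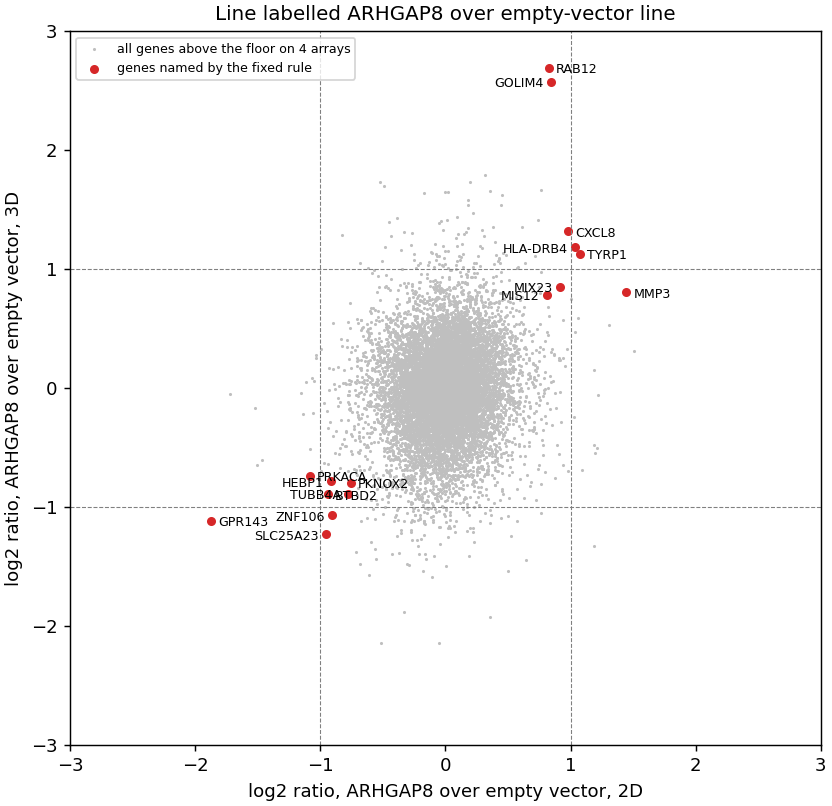
Log2 ratio of the line labelled ARHGAP8 over the empty-vector line in 2D (x axis) and 3D (y axis), 1 point per gene above the floor on all 4 arrays; red points are the genes named by the fixed rule and dashed lines mark 2-fold. TYRP1, CXCL8 and GPR143 lie away from 0 on both axes, while the cloud as a whole has a correlation of 0.111.

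Genes of mitosis and metallothionein genes stood apart as groups between the lines, both higher in the line labelled ARHGAP8. Of 42 measured mitosis genes, 28 were higher in both cultures and 4 lower in both, with list medians of 0.10 in 2D and 0.28 in 3D. None of the 42 passed the test over all genes, and 1 did when adjusted over the list alone; CKS2 was higher by 0.67, BIRC5, an inhibitor of apoptosis that acts in cell division, by 0.55, the kinetochore gene NDC80 by 0.45 and CENPE by 0.41. Metallothioneins, small metal-binding proteins, had medians of 0.45 in 2D and 0.42 in 3D over 7 measured genes; 0 passed over all genes and 4 adjusted over the list alone. MT1X, MT2A, MT1E and MT1H were higher by 0.52, 0.45, 0.44 and 0.45, and since these genes are near-identical copies they are no independent evidence of one another.

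Pigment cell genes as a group had medians below 0 in the line labelled ARHGAP8. Of 30 measured members, 15 were lower in both cultures and 3 higher in both, with medians of -0.31 in 2D and -0.13 in 3D; the 3D median lay at percentile 2.61, just short of standing apart, and the list stood apart as lower after both other scalings. GPR143 fell and TYRP1 rose, 28 did not pass, and adjusted over the list alone 5 fell and 1 rose; GPM6B, a myelin-related membrane protein gene, was at -0.65. Matrix proteases and inhibitors had medians of -0.01 and 0.00 and integrins 0.03 and 0.00, with 0 members past the test over all genes; adjusted over the list alone, 2 matrix proteases or inhibitors rose and 0 integrins passed. Over the 38 lists that did not stand apart, medians ran from -0.31 to 0.22 in 2D and from -0.31 to 0.28 in 3D.

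The second comparison asked how culture in gel differed from culture on plastic. Genes of the cholesterol synthesis list, which also holds genes of fatty acid synthesis, rose in 3D as a group. Of the fatty acid genes, SCD rose by 1.91. FASN did not pass for the culture, at 1.24 in the empty-vector line and -0.39 in the ARHGAP8 line. Of 21 measured members 17 rose and 0 fell, over all genes and adjusted over the list alone, and the list medians were 1.47 in the empty-vector line and 1.30 in the ARHGAP8 line. MSMO1, a sterol methyl oxidase, rose by 2.78 ± 0.16 log2 (moderated SE, 4 arrays), with an adjusted p of 9.23e-10 in limma after Benjamini-Hochberg adjustment. INSIG1, which retains the sterol-sensing complex in the endoplasmic reticulum, rose by 2.51 ± 0.17, ACAT2 by 2.40 ± 0.17 and HMGCS1, the HMG-CoA synthase gene, by 2.20 ± 0.17.

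Genes induced by low oxygen rose as well. Of 30 tested hypoxia genes 16 rose and 0 fell, 18 adjusted over the list alone, with medians of 0.72 and 0.62 over 32 measured genes. DDIT4, an inhibitor of mTOR signalling, rose by 2.14 ± 0.16, the glucose transporter gene SLC2A3 by 2.09 ± 0.20, and the mitophagy gene BNIP3 by 1.34 ± 0.16; its relative BNIP3L was 2.82-fold higher and passed too. Genes of the unfolded protein and ATF4 response had medians of 0.28 and 0.21; 5 of 33 rose and 1 fell, 7 and 2 adjusted over the list alone. ASNS, the asparagine synthetase gene, rose by 1.39, CTH by 0.98 and TRIB3 by 0.83, and DDIT3 was higher by 0.76 without passing.

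Genes of DNA replication and mitosis fell in 3D. Of 40 DNA replication genes 15 fell and 0 rose, 26 falling when adjusted over the list alone, with medians of -0.65 and -0.47. UHRF1, which maintains DNA methylation at replication, fell by 1.38 ± 0.17, CCNE2, an S-phase cyclin, fell by 1.32 ± 0.20, GINS2 fell by 1.26 ± 0.22, although its other probe set read 0.12, and the origin-licensing gene CDC6 fell by 1.11 ± 0.19. Of 42 mitosis genes 14 fell and 0 rose, 22 falling when adjusted over the list alone, with medians of -0.48 and -0.36. FOXM1, a transcription factor of late cell cycle genes, fell by 1.51 ± 0.20, PLK1 fell by 1.09 ± 0.20, BIRC5 fell by 1.08 ± 0.17 and CDC20 fell by 1.02 ± 0.18. Of the 3 other probe sets of BIRC5, 1 went the opposite way, and their median was -0.47. A measure of RNA quality differed between the cultures too, a limit on all culture results. The 3' over 5' signal ratio of ACTB was 1.10 and 1.05 in 2D and 1.23 and 1.32 in 3D in the empty-vector and ARHGAP8 lines. That of GAPDH was 0.874 and 0.899 in 2D and 0.901 and 0.925 in 3D, so for GAPDH the lines differed about as much as the cultures.

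Pigment cell genes had medians of 0.15 and 0.27 and stood apart as higher in 3D; 6 of 30 rose and 0 fell, 7 adjusted over the list alone. The survival gene BCL2A1 rose by 2.15, TYRP1 by 1.47 and GPNMB by 0.71, and CDH19 was higher by 0.74 without passing. Ribosomal protein genes had medians of 0.15 and 0.35, with 1 of 33 rising and 0 adjusted over the list alone, and did not stand apart after quantile normalization; RPL18 and RPS9 were higher by 0.37 each. Targets of YAP and TEAD, which respond to cell spreading, had medians of -0.23 and -0.33, with 2 of 21 falling over all genes and adjusted over the list alone, and did not stand apart after either other scaling. CCN1 fell by 1.09 and AMOTL2 fell by 0.71. All ratios of the ARHGAP8 line in 3D use the array with raised control signals, ribosomal RNA among them. Each of these lists stood apart in the empty-vector line too, by the definition used.

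Outside these lists, BHLHE40, a hypoxia-inducible repressor, rose 3.88-fold and SOD2, the mitochondrial superoxide dismutase gene, by 2.73 log2. FARSB, a phenylalanyl-tRNA synthetase subunit gene, fell by 1.98, although its other probe set read 0.31. TMEM201 fell by 2.27, with a signal of 74.2 on the empty-vector 3D array, close to the floor, and its other probe set read -0.93. MYL9, a myosin light chain gene, fell by 1.82, from ratios of -1.34 in the empty-vector line and -2.29 in the ARHGAP8 line. The matrix glycoprotein gene THBS1 was 2.82-fold lower, past the test, with 2 of its 4 other probe sets opposite. MYBL2 fell by 1.49, CTPS1 of CTP synthesis fell by 1.32 and ODC1 of polyamine synthesis fell by 1.29. Genes at the floor in 2D on both arrays rose, averaged over the lines, by at least 2.09 for the long noncoding RNA BANCR, 1.71 for DEPP1 and 1.44 for LOC154761. In the empty-vector and ARHGAP8 lines the bounds were 1.82 and 2.35 for BANCR, 2.18 and 1.23 for DEPP1 and 1.42 and 1.47 for LOC154761. COL9A1 rose at least 2.82-fold as an average, with bounds of 3.19-fold and 2.50-fold in these lines, while its other probe set read 0.10. Genes at the floor in 3D were LYPD1, BCL7C, NOP14 and MCOLN1, which fell by bounds of 1.95, 1.65, 1.42 and 1.25 averaged over the lines. The smaller bounds, those of the empty-vector line, were 1.88, 1.60, 1.29 and 1.09. Over the 32 lists that did not stand apart, medians ran from -0.30 to 0.33 in the empty-vector line and from -0.42 to 0.37 in the ARHGAP8 line.

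By the additive test 375 genes rose and 550 fell in 3D among 13239. The excess of falling genes depends on the processing, with 264 rising and 291 falling after quantile normalization and 74 and 40 without a floor, while 89 genes passed under all 10 settings tried, MSMO1, DDIT4, FOXM1 and UHRF1 among them. In simulated data a mean of 22.1 of 178.9 culture calls were false, and 4.45 calls were made with no change simulated. By size, 233 genes were at least 2-fold higher and 173 lower in the empty-vector line, and 244 and 262 in the ARHGAP8 line. The rule was met in both lines by 80 higher genes, where independent lists would share 3.98, and 59 lower genes, against 3.17; 2 genes met it in opposite directions, and all 139 passed the additive test. Without the ARHGAP8 3D array the rule rests on the empty-vector line, with 406 genes. The ratios of the lines correlated at 0.480 across 11201 genes, which are not independent replicates.

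**Figure D3:**
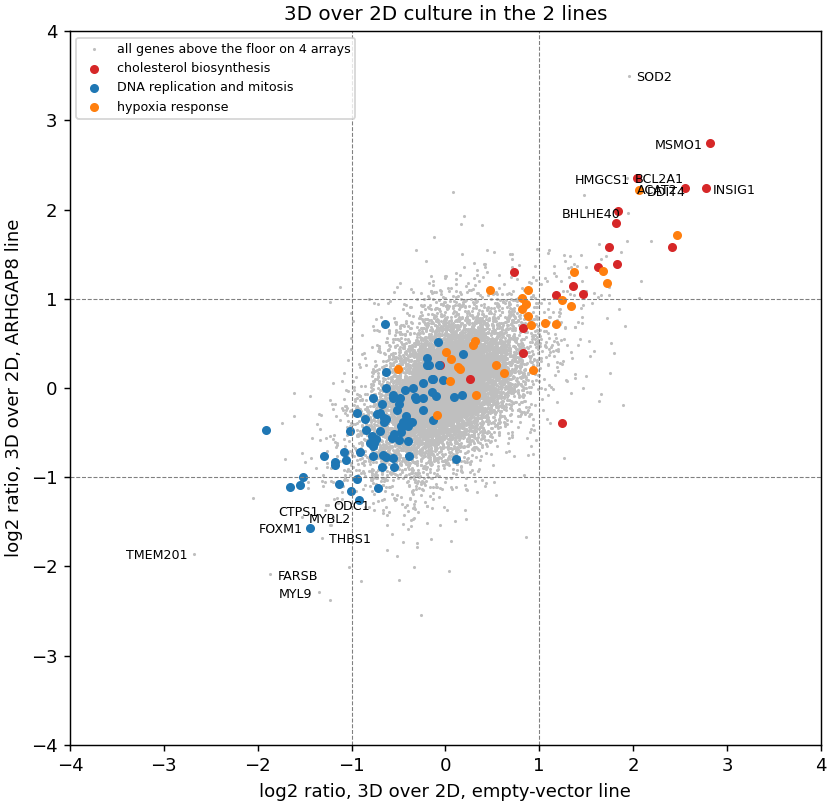
Log2 ratio of 3D over 2D culture in the empty-vector line (x axis) and the ARHGAP8 line (y axis), 1 point per gene above the floor on all 4 arrays, with 3 sets of listed genes coloured and dashed lines at 2-fold. Cholesterol genes such as MSMO1 lie at the upper right, and genes of DNA replication and mitosis mostly lie at the lower left.

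**Figure D4:**
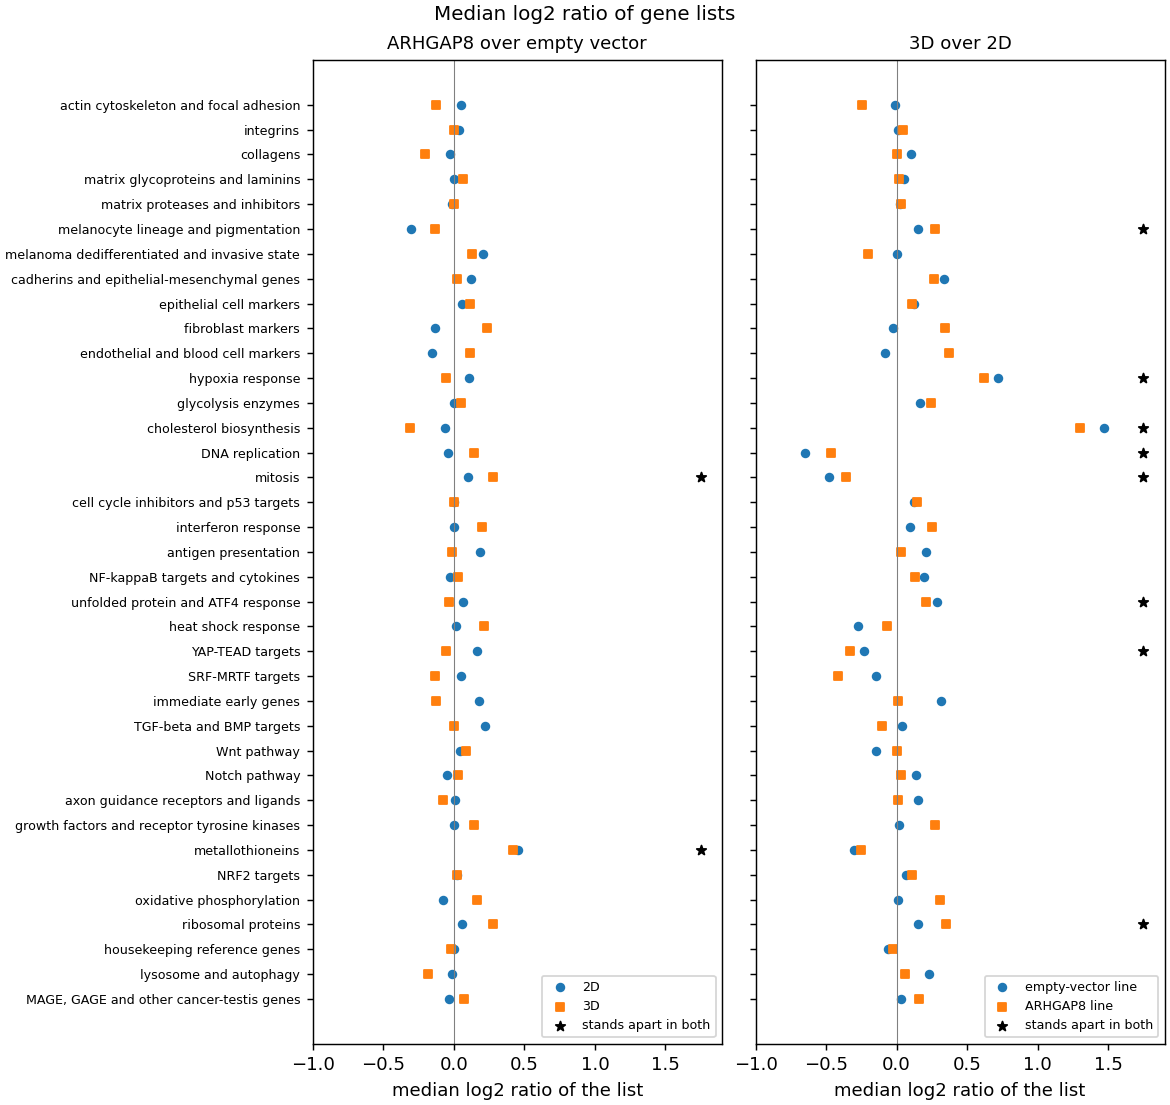
Median log2 ratio of 37 gene lists, between the lines in 2D and 3D (left) and between cultures in each line (right); stars mark lists that stand apart in both ratios. Stars mark 2 lists between the lines and 8 between the cultures, with cholesterol biosynthesis farthest from 0.

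The third comparison asked whether the difference between the lines depended on the culture, and with 1 array per group it gives values without a test. Among 11201 genes above the floor on all arrays, the ratio between the lines was at least 4-fold greater in 3D than in 2D for 3 genes and at least 4-fold smaller for 5. CBX5, which encodes a heterochromatin protein, had log2 ratios of -0.52 in 2D and 1.73 in 3D, and RPLP2, a ribosomal stalk protein gene, -0.83 and 1.29. BPIFA3 had -0.49 and 1.70. Among the 5 on the other side, NPIPA1 had 0.36 and -1.92, SF3A2 -0.05 and -2.14, CDC42EP5 0.65 and -1.44, ZBTB40 1.19 and -1.33, and OGA, which removes O-linked N-acetylglucosamine, 0.50 and -1.54. With the mean of their probe sets the differences of CBX5, ZBTB40 and OGA shrank from 2.25, -2.52 and -2.04 to 0.75, -0.60 and -0.31. These differences thus rest on 1 probe set each. So do those of BPIFA3, RPLP2, NPIPA1 and CDC42EP5, which had no other probe set to compare. Some signals lay close to the floor. They were 75.8 for BPIFA3 on the empty-vector 3D array and 87.3 for CDC42EP5 on the empty-vector 2D array. On the ARHGAP8 3D array they were 76.3 for ZBTB40, 86.0 for SF3A2 and 97.8 for NPIPA1.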

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

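Of the tests in this part, those of another scaling, of the ARHGAP8 3D array alone as the source of the culture pattern, of the interaction and of separate lines were chosen after the result was seen. The tests of array position, histone genes and other probe sets were chosen before.

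The ratio between the lines went opposite ways in 2D and 3D for 8 genes with a large difference of differences, a difference that was not tested. The log2 differences were 2.25 for CBX5, 2.19 for BPIFA3, 2.12 for RPLP2, 1.85 for LOC105370178, -2.52 for ZBTB40, -2.28 for NPIPA1, -2.09 for CDC42EP5 and -2.04 for OGA. Outside the genes compared, 7 groups that hold 49 of the 62 control probe sets had a higher median signal on the ARHGAP8 3D array than on any other. Of the 13 probe sets outside these groups, 6 were highest on that array. The bioB, bioC and bioD hybridisation controls were 1.42 times, the Alu repeat 1.29 times and the cre hybridisation control 1.22 times the highest of the other 3 arrays. The median signals of the other 4 groups there were 626 for 18S ribosomal RNA, 1390 for 28S ribosomal RNA, 245 for the dap control transcript of B. subtilis and 69.3 for its lys, phe and thr transcripts. No fold is given for them, since the 28S medians fall on different probe sets and the others lay below the floor of 72.3 on the other 3 arrays.

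More genes were 2-fold apart between the lines in 3D than in 2D, 331 against 66. Scaling that depends on brightness is argued against, since the ratio of the counts was 4.70 after cyclic loess normalization. Of the 331 genes, the ARHGAP8 3D array lay outside the other 3 arrays for 272 and the empty-vector 3D array for 234, a ratio of 1.16; this met the limit set beforehand against the ARHGAP8 3D array as the cause, but that limit was too weak, since genes chosen for a gap between the 3D arrays put both at the edge and culture alone moves the empty-vector 3D array. A gain of RNA without poly(A) tails stays open. The histone median in 3D, 0.08 log2 at percentile 78.3 of random lists, met the limit set beforehand against it. That limit was too weak, since a median near 0 decides nothing. The 5' and middle probe sets of 28S ribosomal RNA were raised on the ARHGAP8 3D array, at 1390 and 1554, and its 3' probe set was not, at 124. Ribosomal RNA was not the only control raised there. The dap control transcript of B. subtilis had a median of 245 against 50.3 to 64.5 on the other arrays. The bioB, bioC and bioD hybridisation controls were 1.42 times the highest other array. An aberrant ARHGAP8 3D array, a gain of RNA without poly(A) tails, noise shared by both 3D arrays and an effect of the plasmid that depends on culture cannot be told apart, since a model with the interaction has 0 residual degrees of freedom.

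Cholesterol genes were higher and cell division genes lower in 3D. The ARHGAP8 3D array alone is argued against by the empty-vector ratio, which does not use it. Its list medians were 1.47 for cholesterol, -0.65 for DNA replication and -0.48 for mitosis. The cholesterol median of the empty-vector line was 1.14 times that of the ARHGAP8 line. That comparison could hardly have come out otherwise, since the lists were picked for standing apart in both lines. Scaling is argued against by the 4 of 4 lists, cholesterol, hypoxia, DNA replication and mitosis, that still stood apart after cyclic loess normalization. RNA integrity stays open and was not tested as a cause: the 3' over 5' signal ratio of ACTB was higher in 3D, 1.23 and 1.32, than in 2D. An effect of the culture, which the design names, stays open as untested, and cell density and harvest were not analysed here.

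Pigment cell genes had medians below 0 in the line labelled ARHGAP8, but in 3D the list fell short of standing apart, at percentile 2.61, and 28 of 30 members did not pass the test, with 1 higher and 1 lower. Scaling as the whole cause of the 2D median is argued against, since it was -0.33 after cyclic loess normalization, with -0.16 in 3D. A misleading choice of probe set is argued against in 2D for the 18 members with other probe sets to compare. Of their 34 other probe sets 28, or 82.4%, had the sign of the chosen one in 2D. GPR143 and TYRP1 had no other probe set to compare. A difference between separately selected lines that is unrelated to the plasmid cannot be told apart from an effect of ARHGAP8, with 1 line per plasmid.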

How the results depend on the processing

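The test on genes above the floor on all 4 arrays and the counts without the ARHGAP8 3D array were chosen after the data were seen. Of 1896 values of named genes recomputed, 1703 stayed on their side of the threshold or, for differences of differences, near their main value. A further 160 no longer passed, 26 newly passed and 7 differences of differences moved. Reversal was looked for only in values that passed in the main setting and in differences of differences, and 0 reversed. For the other values the direction was not compared. Leaving out an array was not possible for the additive test, since it leaves 0 residual degrees of freedom. Signal over background limits low genes, and counts by size rose as the floor was lowered.

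With the floor at percentile 25, genes 2-fold apart between the lines were 777 in 2D, 1295 in 3D and 90 in both; those between cultures were 1313 in the empty-vector line, 1621 in the ARHGAP8 line and 332 in both, and 159 had a 4-fold difference of differences. Without a floor these counts were 543, 926, 48, 964, 1195, 246 and 146. With the floor at percentile 60, counts between the lines were 30, 201 and 5, and 3 genes had a 4-fold difference of differences. With the mean of a gene's probe sets 39 genes were 2-fold apart in 2D and 4 had such a difference. Quantile normalization split that difference into 4 higher and 4 lower genes, against 3 and 5.

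By construction, fold thresholds move the counts. At 1.5-fold they were 695, 1801 and 107 between the lines and 2119, 2429 and 706 between cultures; at 3-fold they were 6, 26 and 1, and 76, 63 and 24. Without the ARHGAP8 3D array the rule for both cultures reduces to 66 genes and that for both lines to 406, since 1 comparison is left.

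Plasmid calls of limma, 17 in all, were 0 after quantile normalization, 0 after cyclic loess, 0 with the floor at percentile 25 and 0 without a floor, with 997, 1035, 1245 and 1283 genes under an unadjusted p of 0.05. They were 6 with the mean of probe sets, 1 without the trend, 10 with robust eBayes, 18 with the floor at percentile 60 and 61 on genes above the floor on all 4 arrays. In simulated data that last setting made a mean of 16.6 false among 174.0 plasmid calls and 0.85 calls with no change simulated, so how many of the 61 are false is not known. No plasmid gene passed in every setting. Culture calls, 925, were 555 after quantile normalization, 604 after cyclic loess, 114 without a floor and 425 without the trend, and 1071 on genes above the floor on all arrays. Genes rising and falling, 375 and 550, were 264 and 291 after quantile normalization, 291 and 313 after cyclic loess, 213 and 212 without the trend and 74 and 40 without a floor; the cause was not tested.

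The correlation of the ratios between the lines was 0.0439 with the floor at percentile 25, 0.0434 without a floor and 0.150 with the floor at percentile 60; that of the ratios between cultures was 0.334, 0.305 and 0.520. After quantile normalization 4 lists stood apart between the lines, against 2.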

Other observations

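No test in this part was chosen after the result was seen; MLANA, TYR and CCND1 were picked after their values were seen, as was the ratio between the lines of DKK1, a gene named by the fixed rule for its culture values.

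MLANA, a melanoma antigen of melanosomes, was at -1.72 log2 between the lines in 2D and at -0.05 in 3D, and TYR, the tyrosinase gene, at -0.82 and 0.04. CCND1, a G1 cyclin gene, was higher in the line labelled ARHGAP8 by 0.98 in 2D and at -0.70 in 3D, and DKK1, a secreted Wnt inhibitor gene, by 1.19 in 2D and at -0.48 in 3D. Whether these ratios differ between cultures was not tested. In the additive test none of MLANA, TYR, CCND1 and DKK1 passed for the plasmid. Averaged over the lines, DKK1 fell by 1.32 in 3D, with an adjusted p of 0.00998 in limma after Benjamini-Hochberg adjustment. CCND1 fell by 1.17, and MLANA and TYR rose by 1.01 and 0.88. By the ratios above, each of these culture changes was larger in the ARHGAP8 line than in the empty-vector line. The averages thus lean on the 2D and 3D arrays of the ARHGAP8 line. For each of these genes the larger gap between the lines lay in 2D. The ARHGAP8 3D array, whose control signals differed, is thus not singled out by these ratios.

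Several lists lay at the edge of the random lists in 1 ratio alone. Immediate early genes had a median of 0.18 between the lines in 2D and -0.13 in 3D, and TGF-beta and BMP targets 0.22 and 0.00. Genes of the dedifferentiated melanoma state had 0.21 and 0.13, with AXL, a receptor tyrosine kinase, at bounds of 0.57 and 1.78, since the empty-vector line was at the floor. Oxidative phosphorylation genes had -0.08 and 0.16. Between cultures, SRF and MRTF targets had -0.15 in the empty-vector line and -0.42 in the ARHGAP8 line; in the additive test over both lines 6 of 22 fell, and 7 fell and 1 rose adjusted over the list alone. Actin and focal adhesion genes had -0.01 and -0.25, with TPM1 falling by 1.07. Markers of other cell types were low in number. Fibroblast markers had -0.03 and 0.35 between cultures over 9 measured genes, endothelial and blood cell markers -0.08 and 0.37 over 8, and epithelial markers 0.13 and 0.11 over 12, of which KRT18 fell by 1.13.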
